A study of Mus musculus with 6 samples.

How the data were processed

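RNA from sorted mouse bone marrow cells was sequenced in 6 libraries of 4 groups. The mice, of the C57BL/6 strain, carried CBL and RUNX1 mutations that model myelodysplastic syndrome, and were given Mdivi-1 or its vehicle. Hematopoietic stem and progenitor cells (HSCPs) were enriched through the surface receptor CD117 and the mutant clone was sorted by flow cytometry, per the labels. Mutant Ly6G+ myeloid cells, mostly of the neutrophil lineage, were sorted from the same tissue. Each HSCP arm held 1 library and each Ly6G+ arm held 2. The labels state that marrow came from individual mice but do not tie each library to a mouse, so p-values measure the spread between these libraries.

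The authors deposited 1 table of 28987 mouse genes in TPM, a length-corrected share of all transcripts. Its name speaks of counts, yet the values are not whole numbers and each library sums to between 963243.1 and 979168.3, so they were treated as TPM. Per the submitters' processing notes, the tools were bcl2fastq, CASAVA 1.8 and kallisto, and the genome build was mm10. The kallisto version, the transcript annotation and the step from transcripts to genes are not given in the sources used here. Strand was not stated either, so a gene and its antisense partner cannot be separated with confidence. TPM carries no read totals, so depth is unknown and no counting interval is given. Among genes below 0.3 TPM, values of the same gene in a pair of libraries cluster at fixed ratios, which were read as the relative worth of 1 read. Relative to HSCP vehicle this worth was 1.05 in HSCP Mdivi-1, 1.18 and 1.05 in Ly6G+ vehicle, and 0.979 and 0.946 in Ly6G+ Mdivi-1.

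Gene identifiers were matched to GENCODE M21, whose positions are on the same assembly as mm10. This gave a symbol and position to 27458 genes and left 1529 without a symbol, and 9040 genes were at 0 in every library. For each gene, the percentage of 31-mers found in no other gene was counted from the M21 transcripts, as a measure of reads that kallisto has to share between similar genes. In every pair of libraries, 0 genes with 1 TPM or more in either held identical values.

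The planned test was for counts. Because the deposited values are TPM, the fallback written for normalized values was used: limma 3.58.1 in R 4.3.3, on log2(TPM + 1), with a trended and robust prior, over genes with at least 1 TPM in at least 2 of the libraries compared. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are therefore on the log2(TPM + 1) scale, which understates changes of low genes. The treatment test in Ly6G+ used 4 libraries and left 2 residual degrees of freedom. The test between populations used all 6 libraries with treatment as a covariate and left 3. The HSCP arms have no replicates, so no p-value was computed there. Genes were counted when the log2 ratio was at least 1 in size and the mean was at least 10 TPM, and each gene list was placed among 10000 random lists of the same size, matched on expression in 20 bins.

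Before the data were examined, 45 gene lists with 1289 genes were fixed, of which 1255 genes are in the table. They comprise 31 process lists and 14 lists of markers of blood cell types that the sorts could hold. Lists of at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. A call by camera says that a list moved relative to the other genes tested. The genes named were also set by a rule fixed then. Dnm1l, Kit and Ly6g are always given. For each test, up to 10 genes per direction with the largest change were taken among those past the threshold. They needed a mean of at least 5 TPM, groups that did not overlap and an established symbol. In HSCP the 10 largest ratios per direction at a mean of at least 10 TPM were taken. Up to 4 members per list were eligible, first those past the test by size of change, then those most expressed. Other named genes are marked where they appear as chosen after their values were seen.

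On simulated tables built from these libraries, the Ly6G+ test (11775 genes) recovered 65.4% of genes changed by 0.5 on the log2 scale, 96.7% at 1 and 98.8% at 2. Unchanged genes made up 8.8% of its calls, above the nominal 5%. The test between populations (12338 genes) recovered 67.8%, 97% and 98.2%, with 7.6% of its calls on unchanged genes. Only genes at a mean level of about 5 TPM or more were changed, so recovery of lower genes was not measured. Noise was normal, with each gene's SD after shrinkage by the prior, and these rates apply to noise of that form. A list of 30 genes moved by 0.3 was called in 20 of 20 tables, with 0 calls of other lists. Noise in these tables was drawn for each gene separately. The result therefore does not show how camera's preset correlation performs where genes of a list vary together. In the HSCP step, a list moved by 0.3 passed the upper bound in 10 of 10 tables, and 5.5% of unmoved lists fell outside the central 95%. Ratios were shuffled over genes there, so that share also applies only to genes that vary independently.

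Alternatives included other scalings, pseudocounts, filters, thresholds, gene classes, each library left out, and replicate number as a block. Bootstrap intervals used 10000 draws and permutation tests 100000. The bootstrap drew the genes of a list, treats them as independent, and carries no spread between libraries. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.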

Results

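Gene expression was measured by RNA sequencing in mutant bone marrow cells of mice with CBL and RUNX1 mutations, a model of myelodysplastic syndrome, given Mdivi-1 or vehicle. Mdivi-1 is a small molecule described as an inhibitor of Drp1, the dynamin-like GTPase that divides mitochondria and is encoded by Dnm1l. HSCPs, the immature cells that carry the stem cell factor receptor CD117 (gene Kit), gave 1 library per treatment. Ly6G+ cells, which bear a surface protein of maturing neutrophils, gave 2 libraries per treatment. The design asks how the treatment altered expression in each population, and how the populations differ.

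The calprotectin genes S100a8 and S100a9 together held 7.7% and 7.06% of TPM in HSCP vehicle and Mdivi-1, against 20.93%, 19.69%, 19.75% and 20.95% in the Ly6G+ libraries. Between 11456 and 11930 genes reached 1 TPM in each library. Pearson's r across all 28987 genes on the log2 scale was 0.994 within each Ly6G+ arm and 0.991 to 0.992 between arms, where genes are not independent replicates. The 9040 genes at 0 in every library were included, which raises r. Dnm1l (chromosome 16, 16312230 to 16358959, mm10) stood at 30.6 TPM in HSCP vehicle and 35.5 in HSCP Mdivi-1. In Ly6G+ it was 23.7 ± 0.846 TPM with vehicle and 23.8 ± 1.11 with Mdivi-1 (SD, n = 2), a log2 change of 0.01 (limma adjusted p = 0.975). Between populations its log2 change was -0.46 (limma adjusted p = 0.00219), which became -0.09 after median-of-ratios scaling (limma adjusted p = 0.298). In Ly6G+, Kit went from 12.3 ± 2.64 to 9.13 ± 0.56 TPM with Mdivi-1 (log2 change -0.37, limma adjusted p = 0.223) and Ly6g from 827 ± 18.1 to 716 ± 105 TPM (log2 change -0.22, limma adjusted p = 0.276; SD, n = 2). In HSCP vehicle and Mdivi-1, Kit stood at 72.2 and 64.9 TPM (log2 ratio -0.15) and Ly6g at 187 and 90.1 TPM (log2 ratio -1.04).

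In Ly6G+ cells, the largest rises under Mdivi-1 among genes that met the naming rule included the phosphatase gene Dusp1 and the decoy receptor gene Il1r2. Dusp1, whose product switches off MAP kinases (chromosome 17, 26505590 to 26562128), went from 21.4 ± 0.208 to 131 ± 3.41 TPM (SD, n = 2), a log2 change of 2.55 with SE 0.059 (limma adjusted p = 0.000734). Il1r2, whose product binds interleukin-1 without signalling (chromosome 1, 40074079 to 40125231), went from 33.8 ± 0.726 to 199.5 ± 7.41 TPM, a log2 change of 2.53 with SE 0.06 (limma adjusted p = 0.000734). Socs3, an inhibitor of cytokine receptor signalling, rose by 1.96 (limma adjusted p = 0.01), and Nab2, a corepressor of EGR transcription factors with 62.1% unique 31-mers, rose by 2.72 (limma adjusted p = 0.00188). As a group, the 19 genes of ERK and cytokine receptor feedback tested, which include Socs3, did not rise: 1 rose, 1 fell and 17 did not pass (adjusted over the list alone, 4 rose and 8 fell; median -0.15; limma camera adjusted p = 0.597). The acute-phase gene Saa3 rose by 2.18, the metalloreductase gene Steap4 by 1.93 and the arrestin-domain gene Arrdc3 by 1.92. The largest rise that met the naming rule was that of Hotairm1, a non-coding RNA of the HoxA cluster (chromosome 6, 52156902 to 52162119), from 0.266 ± 0.172 to 11.2 ± 1.83 TPM (log2 change 3.26, limma adjusted p = 0.00433), although its antisense position leaves the strand of these reads open. The immunoglobulin kappa segments Igkv1-115 and Igkj2 rose by 1.94 and 1.70, and such segments share reads with related copies.

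Genes of early B cells were among the largest falls that met the naming rule in the Mdivi-1 libraries of the Ly6G+ sort. Igll1 and Vpreb1, which form the surrogate light chain of the pre-B cell receptor on chromosome 16, went from 29.4 ± 1.01 to 1.07 ± 0.585 TPM and from 26.1 ± 3.83 to 2.23 ± 0.524 TPM (SD, n = 2). Their log2 changes were -3.91 (limma adjusted p = 0.00395) and -3.07 (limma adjusted p = 0.00395), and Vpreb1 has 63.4% unique 31-mers. Vpreb3 fell by 3.26 and Cd79a, a signalling chain of the B cell receptor, by 2.63. The IgG1 constant region Ighg1 fell by 3.65 and belongs to the plasma cell list, where 2 genes rose and 3 fell. Crygn, a lens crystallin gene (chromosome 5, 24751003 to 24758008), was at 103 and 175 TPM with vehicle and was listed at 0 and 0.778 with Mdivi-1 (log2 change -6.67, limma adjusted p = 0.00477). Bfsp2, which encodes a lens filament protein, fell by 2.73 and the membrane protein gene Pdzk1ip1 by 2.11. The basophil protease gene Mcpt8 (chromosome 14, 56082166 to 56085273) went from 249 ± 0.183 to 67.8 ± 4.26 TPM (log2 change -1.86, limma adjusted p = 0.00188), and the interferon-inducible GTPase gene Iigp1 fell by 1.99.

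**Figure D1:**
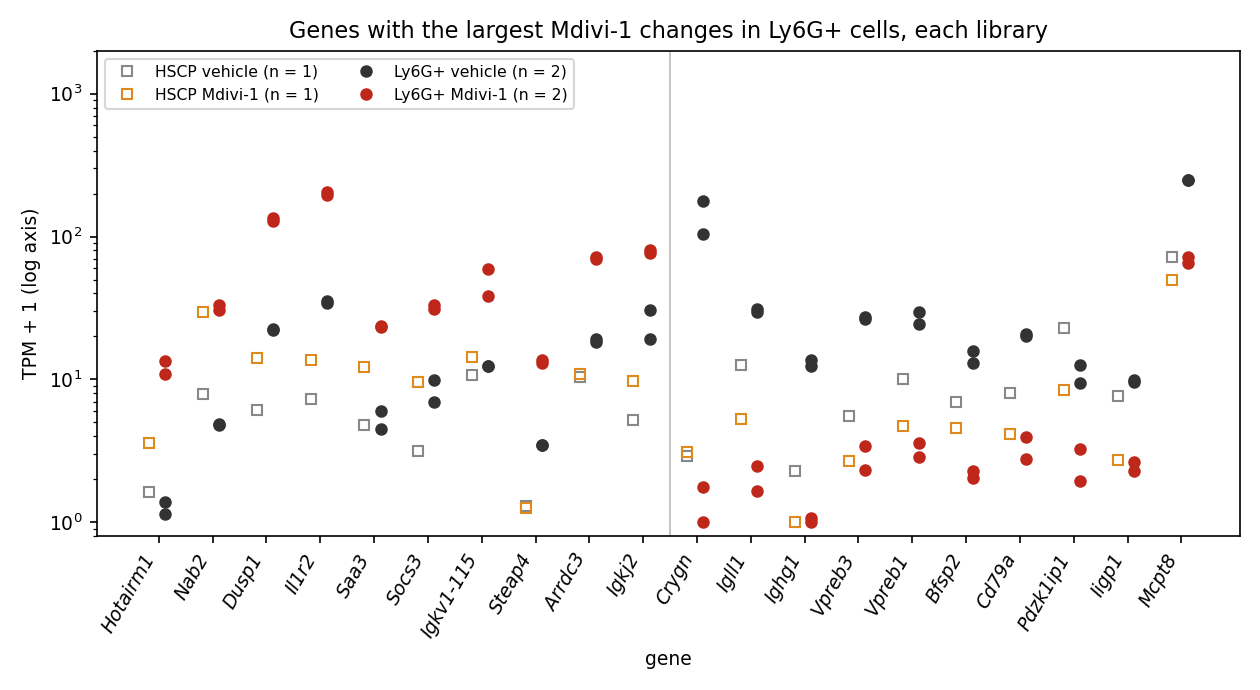
TPM plus 1 on a log axis for the 20 genes named by rule for the Mdivi-1 test in Ly6G+ cells (past the threshold, mean of at least 5 TPM, no overlap between arms, established symbol), 10 higher on the left and 10 lower on the right, where each point is 1 library. Crygn lay at 103 and 175 TPM in the Ly6G+ vehicle libraries, above the 0 and 0.778 of the Mdivi-1 libraries.

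Across 11775 genes tested in Ly6G+, 290 were higher and 499 lower with Mdivi-1, and 3026 had an unadjusted p under 0.05 in limma. Of the calls, 69 higher and 106 lower changed at least 2-fold. The share of calls that were higher was 36.8% on TPM as deposited, 49.1% after median-of-ratios scaling and 50.3% after upper-quartile scaling. The total of 789 dropped when any library was left out. Every main call tested in those fits kept its direction. The calls were chosen with these same libraries, so a kept direction is no separate support for them.

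Interferon-stimulated genes fell in Ly6G+ cells with Mdivi-1. Of 57 members tested, 33 fell, 1 rose and 23 did not pass, and adjusted over the list alone 48 fell and 2 rose. Iigp1, the interferon-induced gene Ifi44 (-1.76) and the chemokine gene Cxcl10 (-1.49) fell most. Ifitm1, which encodes a membrane protein that blocks virus entry, rose by 1.10. Isg15, a ubiquitin-like modifier, fell by 0.74, and was eligible by name through its HSCP ratio rather than through this test. The list's median log2 change was -0.44 (limma camera adjusted p = 1.02e-14; adjusted p = 0.182 with an estimated correlation).

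Markers of some other blood cells fell beside them in the same libraries. Not called were the eosinophil list (1 higher, 0 lower, median -0.002), the monocyte and macrophage list (4 and 4, median -0.01) and the plasma cell list (2 and 3, median 0.04). In the B cell list 19 of 25 members fell and 1, the kappa constant region Igkc, rose (adjusted over the list alone, 22 and 1; median -1.32; limma camera adjusted p = 1.18e-15). In the megakaryocyte list 17 of 25 fell (20 adjusted over the list alone; median -0.88; limma camera adjusted p = 1.15e-12), among them Mmrn1 (-2.23), which encodes a platelet granule protein, von Willebrand factor Vwf (-1.76) and the platelet glycoprotein gene Gp5 (-1.44). Of 15 mast cell and basophil genes 9 fell and 1 rose (adjusted over the list alone, 10 and 2; median -0.58; limma camera adjusted p = 0.00037), with the IgE receptor chain Fcer1a at -1.52 and the basophil protease Prss34 at -1.46. Of 19 dendritic cell genes 9 fell and 1 rose (adjusted over the list alone, 9 and 1; median -0.59; limma camera adjusted p = 1.32e-05), including the lectin gene Cd209a (-1.34) and the transcription factor gene Spib (-1.25). Of 11 genes of MHC class II presentation 5 fell (8 adjusted over the list alone; median -0.56; limma camera adjusted p = 0.00037), among them the invariant chain Cd74 (-0.97) and the class II chains H2-Eb1 (-0.88) and H2-Aa (-0.84). Cd74, H2-Eb1 and H2-Aa are also members of the dendritic cell list, so the falls of those lists are not separate results. With an estimated correlation, adjusted p = 0.182 for the B cell and megakaryocyte lists and adjusted p = 0.277 for the other 3 lists.

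Smaller shifts went the same way in 4 further lists. Of 24 stem and multipotent progenitor genes 8 fell and 2 rose (adjusted over the list alone, 13 and 2; median -0.50; limma camera adjusted p = 0.000481), with the transcription factor gene Gata2 at -1.59. That list shares Vwf with the megakaryocyte list. Gata2 is also in the mast cell and basophil list and in the list of myeloid transcription factors. Of 32 erythroid genes 6 fell (8 adjusted over the list alone; median -0.23; limma camera adjusted p = 0.00141), among them the water channel gene Aqp1 (-0.63) and the beta globin gene Hbb-bt (-0.55). Of 27 myeloid transcription factors 4 fell and 1 rose (adjusted over the list alone, 9 and 3; limma camera adjusted p = 0.0375), where the granulocyte factor gene Cebpe fell by 0.74 and Id2, an inhibitor of helix-loop-helix factors, rose by 0.98. Of 19 T and NK cell genes 2 fell and 1 rose (adjusted over the list alone, 4 and 1; limma camera adjusted p = 0.0334), with the interleukin-7 receptor gene Il7r at -1.10 and the granzyme gene Gzma at 1.78. With an estimated correlation, adjusted p = 0.448, adjusted p = 0.277, adjusted p = 0.632 and adjusted p = 0.543, in that order. The myeloid transcription factor list (fry adjusted p = 0.107) and the T and NK cell list (fry adjusted p = 0.0573) were not called by fry.

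Genes of late neutrophil maturation rose. Of 33 members tested 22 rose, 1 fell and 10 did not pass, and adjusted over the list alone 24 rose and 1 fell (median 0.45; limma camera adjusted p = 3.23e-17; adjusted p = 0.182 with an estimated correlation). Examples are Il1r2, Wfdc17 (1.55), a gene of activated myeloid cells, and the cystatin-type protease inhibitor genes Stfa2l1 (1.35) and Stfa2 (1.32), which share reads with related stefins. Granule genes of earlier stages went both ways. Among 22 secondary granule genes 7 fell and 3 rose (adjusted over the list alone, 12 and 4), with the cathelicidin gene Camp at -0.65, Ngp at -0.53 and haptoglobin Hp at 0.61, and the list was not called (limma camera adjusted p = 0.159). Among 13 primary granule genes 3 fell (adjusted over the list alone, 5 fell and 1 rose; limma camera adjusted p = 0.532), namely the ficolin gene Fcnb (-0.87), Cebpe and the lysozyme gene Lyz2 (-0.44), while Mpo was at 0.07 (limma adjusted p = 0.438).

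Genes of the organelle that Mdivi-1 is aimed at showed few calls. Among 16 mitochondrial fission genes 1 fell, Mtfr1l (-0.37, limma adjusted p = 0.0465), and that call was lost under both other scalings at nearly the same size (-0.32, adjusted p = 0.0543, after median-of-ratios scaling and -0.32, adjusted p = 0.0538, after upper-quartile scaling; adjusted over the list alone, 1 fell; limma camera adjusted p = 0.789). Of 15 fusion and cristae genes and 17 mitophagy genes 0 passed in limma over all genes, and adjusted over the list alone 0 fusion genes passed while 4 mitophagy genes rose and 3 fell (limma camera adjusted p = 0.209 for each list). Of 75 nuclear genes of oxidative phosphorylation 1 fell, Ndufv3 (-0.29, limma adjusted p = 0.0498; adjusted over the list alone, 0), which became -0.24 (adjusted p = 0.0697) and -0.23 (adjusted p = 0.0737) under those scalings, and of 13 genes of the mitochondrial genome 0 passed, also when adjusted over the list alone (limma camera adjusted p = 0.64 and 0.551). The medians of these last lists were -0.02 on TPM as deposited and turned to 0.03 after median-of-ratios scaling. Among 22 genes of the unfolded protein response 3 rose, the endoplasmic reticulum chaperone genes Calr (0.32), Hspa5 (0.31) and Hsp90b1 (0.31), and adjusted over the list alone 5 rose and 1 fell (limma camera adjusted p = 0.000428; adjusted p = 0.277 with an estimated correlation). That list was not called by fry (fry adjusted p = 0.0558). Without an expression filter Calr, Hspa5 and Hsp90b1 did not pass (limma adjusted p = 0.109, 0.0784 and 0.0762), while all of them passed under both other scalings.

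**Figure D2:**
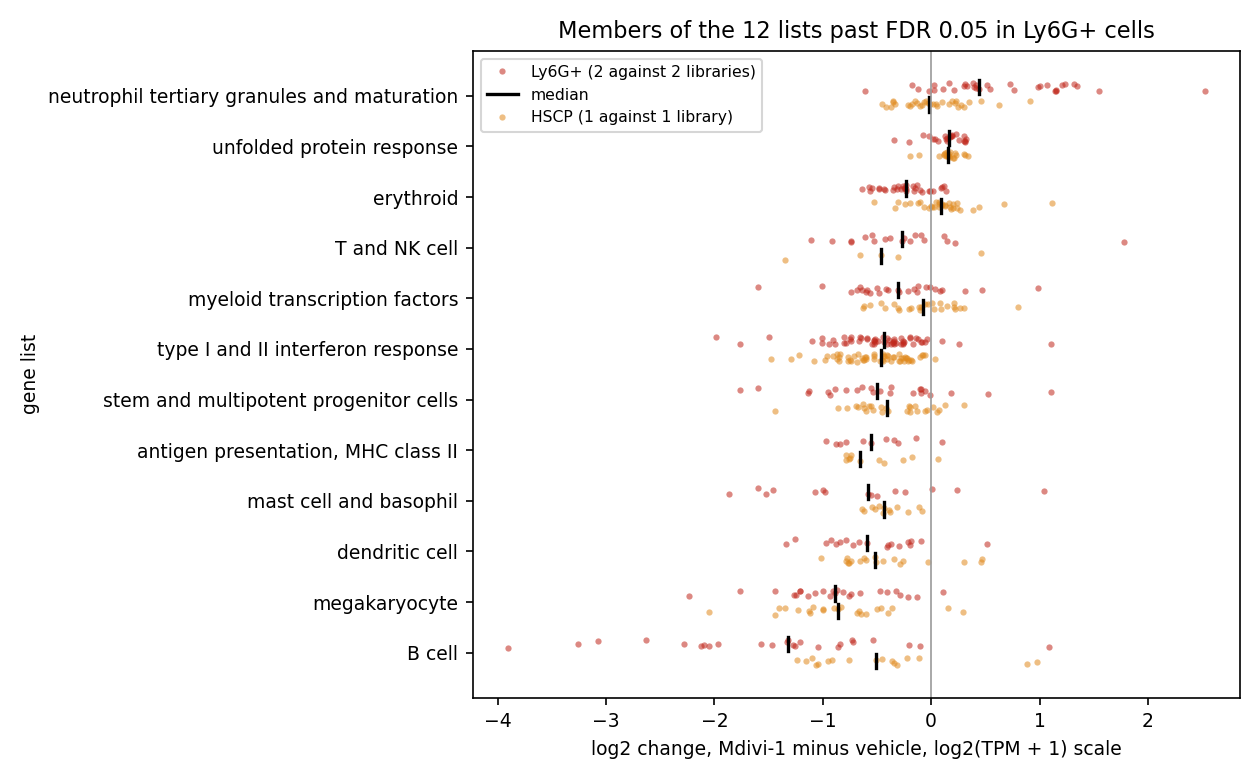
Log2 change with Mdivi-1 of each member of the 12 gene lists called in Ly6G+ cells, for Ly6G+ (2 against 2 libraries) and for HSCP (1 against 1 library), with a bar at each median. The interferon medians were -0.44 in Ly6G+ and -0.47 in HSCP, and the maturation medians were 0.45 in Ly6G+ and -0.02 in HSCP.

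Between populations, lists of neutrophil maturation and secondary granules were higher in Ly6G+, and lists of ribosomes and S phase were higher in HSCP. With an estimated correlation none of these calls held (limma camera, adjusted p = 0.254 for maturation and for secondary granules, adjusted p = 0.226 and adjusted p = 0.258 for the cytoplasmic and mitochondrial ribosome, adjusted p = 0.391 for S phase). The cell surface markers used for sorting differed: Kit was at 68.6 ± 5.17 TPM in HSCP (SD, n = 2 over both treatments) and 10.7 ± 2.38 in Ly6G+ (SD, n = 4), and Ly6g at 138 ± 68.2 and 772 ± 88.9 TPM. Their log2 changes were -2.59 (limma adjusted p = 1.51e-05) and 2.56 (limma adjusted p = 9.05e-05). Among genes that met the naming rule, the largest rises were those of Stfa2 (4.22), Stfa2l1 (4.17), interleukin-1 beta Il1b (4.09) and the resistin-like gene Retnlg (4.05), followed by the kappa segment Igkv11-106 (3.86) and Phospho1 (3.65), a phosphatase gene with only 12.9% unique 31-mers. The collagenase gene Mmp8 (3.63), the arginase gene Arg2 (3.61), the surface receptor gene Cd101 (3.59) and the interleukin-36 gene Il1f9 (3.56) completed the set. The largest falls under that rule were in myeloperoxidase Mpo, from 6148 ± 169 TPM in HSCP to 698 ± 27.4 in Ly6G+ (log2 change -3.14, limma adjusted p = 2.58e-06), in the eosinophil granule genes Epx (-3.06) and Prg2 (-2.99), and in the serine protease genes Elane (-2.97), Prtn3 (-2.88) and Ctsg (-2.64). The mucin gene Muc13 (-2.73), the receptor gene Cd27 (-2.73), the cystatin gene Cst7 (-2.72) and the growth regulator Myc (-2.64) fell as well.

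Of 12338 genes tested, 2736 were higher and 6202 lower in Ly6G+, and 9235 had an unadjusted p under 0.05 in limma. The higher share was 30.6% on TPM as deposited, 49.8% after median-of-ratios scaling, with 4156 genes higher, and 46.5% after upper-quartile scaling. The median log2 change of all genes moved from -0.35 to -0.01 and -0.07 under those scalings, so list medians in this comparison are given relative to the all-gene median on TPM as deposited.

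Maturation genes rose in 32 of 33 cases (3.07 above the all-gene median) and secondary granule genes in 20 of 22 (1.66 above), with the same counts adjusted over the list alone. The phagocyte NADPH oxidase list rose in 6 of 7 (1.42 above), including Cybb, and the alarmin list in 9 of 11 with 2 lower, including S100a6. Toll-like receptor and inflammasome genes rose in 23 of 31 with 2 lower (1.26 above), among them Tlr13, Tlr2 and the interleukin-1 antagonist Il1rn. Interferon-stimulated genes rose in 45 of 58 with 5 lower, and 46 rose adjusted over the list alone (1.14 above; limma camera adjusted p = 1.42e-14; adjusted p = 0.0921 with an estimated correlation). Examples are Rtp4 (2.37), the antiviral gene Rsad2 (2.09), Ifi27l2a (1.99) and Ifit1 (1.99). TNF and NF-kB genes rose in 25 of 44 with 7 lower and immediate early genes in 17 of 22 with 4 lower. T and NK cell genes rose in 11 of 19 with 1 lower, TGF-beta genes in 11 of 19 with 4 lower, monocyte genes in 17 of 30 with 9 lower and mast cell and basophil genes in 8 of 15 with 2 lower. Primary granule genes went both ways, 3 higher and 8 lower of 13, and that list was not called (limma camera adjusted p = 0.216).

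Genes of protein synthesis, respiration and DNA replication were lower in Ly6G+. All 74 cytoplasmic ribosome genes fell (-1.04 relative to the all-gene median), led by Rps28 (-2.49) and Rpl12 (-2.33), as did 73 of 75 mitochondrial ribosome genes (-0.74), with Mrps28 at -2.22. Nuclear genes of oxidative phosphorylation fell in 69 of 75 cases (70 adjusted over the list alone; -0.47), among them Atp5k (-2.37) and Uqcr11 (-1.80), mitochondrial genome genes in 12 of 13 with 1 higher (-0.35), and fusion and cristae genes in 13 of 15 with 1 higher (-0.47). Citric acid cycle genes fell in 19 of 20 with 1 higher, including Idh2 (-1.91), fatty acid oxidation genes in 17 of 20 with 1 higher and proteasome genes in 30 of 31. After median-of-ratios scaling the lower counts were 52 for oxidative phosphorylation (with 5 higher), 8 for the mitochondrial genome (with 1 higher), 10 for fusion and cristae (with 1 higher), 12 for the citric acid cycle (with 1 higher), 11 for fatty acid oxidation (with 2 higher) and 21 for the proteasome. All 45 S phase genes fell (-0.84), with the uracil glycosylase gene Ung at -2.10 and the replication factor gene Gins2 at -1.81. Of 59 G2 and M phase genes 50 fell, but after median-of-ratios scaling 17 fell and 7 rose. Progenitor genes fell in 20 of 28 cases with 3 higher (-0.75), among them Sox4 (-2.40) and Cd34 (-2.30). Erythroid genes fell in 25 of 32 with 1 higher (28 adjusted over the list alone), heat shock genes in 16 of 18, unfolded protein response genes in 17 of 22 with 2 higher and lipid synthesis genes in 20 of 28 with 2 higher. After median-of-ratios scaling these counts were 21 lower with 2 higher, 14 with 1, 14 with 5 and 16 with 6.

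In total 29 of the 45 lists were called between populations by limma camera, with adjusted p up to 0.04, and 0 were called with an estimated correlation, where 8 had an unadjusted p under 0.05 and adjusted p among the called lists ran from 0.0921 to 0.651. The B cell call (limma camera adjusted p = 0.019) was lost after median-of-ratios scaling (0.134) and without the HSCP vehicle library (0.888), and the mitophagy list, with 8 members higher and 3 lower, changed direction under fry.

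**Figure D3:**
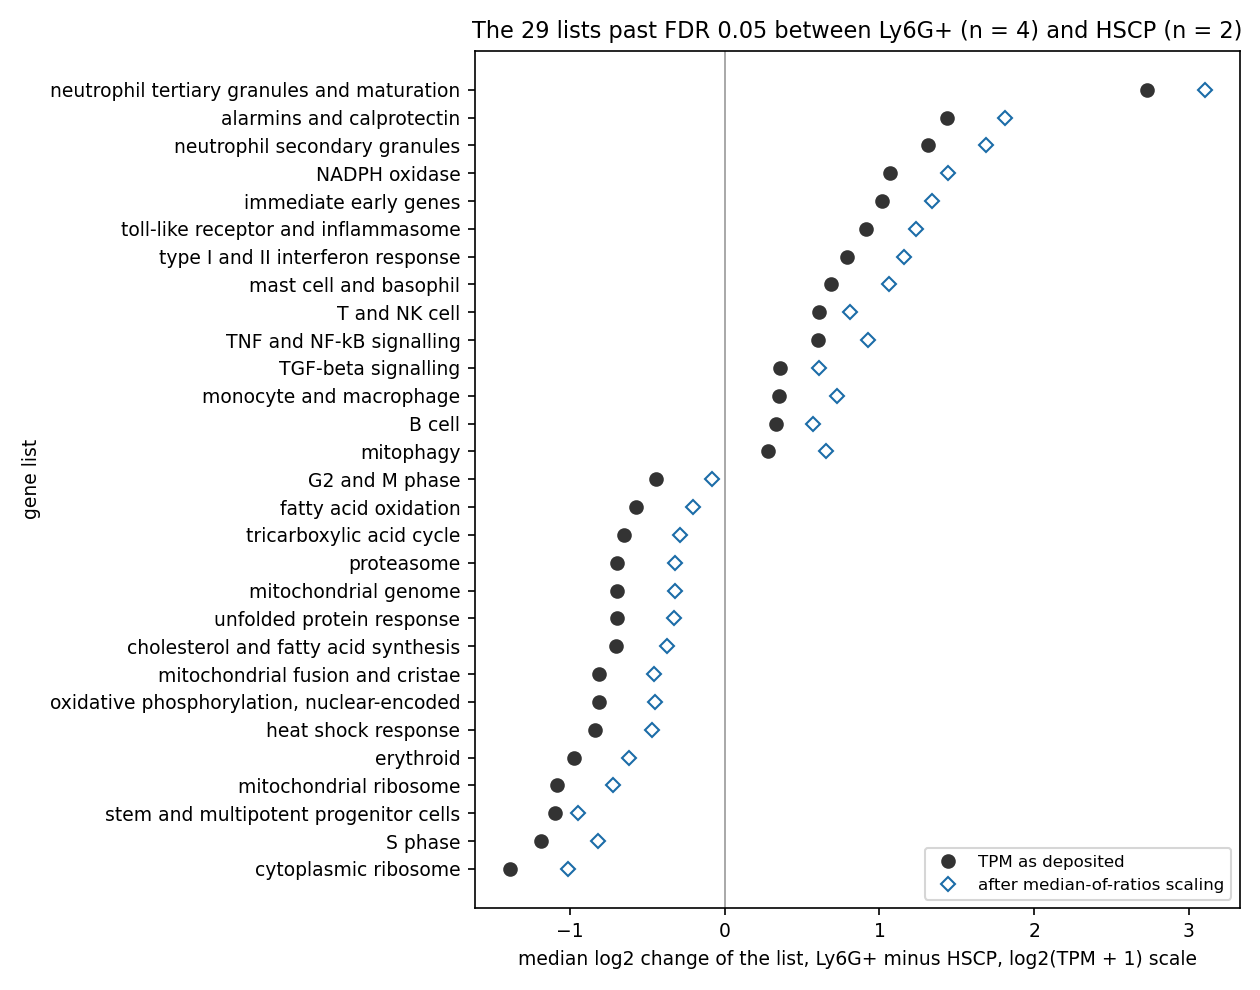
Median log2 change between Ly6G+ (n = 4) and HSCP (n = 2) for the 29 lists called, on TPM as deposited (filled circles) and after median-of-ratios scaling (open diamonds). The maturation list stood at 2.73 and 3.10 and the cytoplasmic ribosome list at -1.39 and -1.01.

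In HSCP the treatment arms held 1 library each, so the values describe those 2 libraries and have no replicate check. Of 7987 genes at a mean of 10 TPM or more, 31 were at least 2-fold higher and 43 at least 2-fold lower with Mdivi-1. These counts were 15 and 34 for protein-coding genes alone, and 15 and 29 for genes with at least 80% unique 31-mers. The highest ratio was that of Ran, the GTPase of nuclear transport, at 306 TPM with vehicle and 2692 with Mdivi-1 (log2 ratio 3.13). Nab2 followed, at 6.96 and 28.8 TPM (1.91), then the acetyl-CoA carboxylase gene Acaca at 10.9 and 33.1 TPM (1.52) and the deadenylase gene Cnot8 (1.46). Tmem141, Scaf1, the asparagine synthetase gene Asns, Mrpl23, the clock gene Per1 and Insl3 had ratios from 1.40 to 1.07. The lowest ratio was that of S100a13, at 60.3 and 0.0921 TPM (-5.81), and its Ly6G+ vehicle libraries stood at 24.3 and 0.018 TPM. Mpp1, which encodes an erythrocyte membrane protein, was at 514 and 110 TPM (-2.22), and Efcab7 (-2.05), Gabbr1 (-2.04), March8 (-1.87), Dusp12 (-1.79), Golga5 (-1.64), Zfp691 (-1.54), Cnot6l (-1.51) and Pdzk1ip1 (-1.43) were lower. Of the genes named here, S100a13, Zfp691 and Acaca had the largest SE of the difference in change between populations (4.58, 1.81 and 1.49). That SE rests on the spread between Ly6G+ replicates, so their HSCP ratios may be no more than spread between libraries. The same size rule between replicates of 1 arm in Ly6G+ gave 31 genes for vehicle and 38 for Mdivi-1, and between Mdivi-1 and vehicle libraries it gave 105 to 123.

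As lists, 27 of 45 lay outside the central 95% of random lists in HSCP. Interferon-stimulated genes had negative ratios for 57 of 58 members, with a median of -0.47 at percentile 0.0, and Isg15 was at 44.9 and 20.6 TPM. Megakaryocyte genes were negative for 21 of 23 (median -0.86), with Gp5 at 18.6 and 7.36 TPM and Pf4, platelet factor, at 149 and 74.3 TPM. MHC class II genes were negative for 10 of 11 (-0.66), eosinophil genes for 9 of 9 (-0.60), dendritic cell genes for 16 of 19 (-0.52), B cell genes for 15 of 17 (-0.51) and progenitor genes for 23 of 28 (-0.41). The MHC class II and dendritic cell lists share Cd74, H2-Aa, H2-Ab1 and H2-Eb1. On the other side, integrated stress response genes were positive for 21 of 28 (median 0.29, above the random lists), led by Asns and by Ddit4 at 8.32 and 18.5 TPM, unfolded protein response genes for 20 of 22 (0.16) and proteasome genes for 31 of 31 (0.17, percentile 99.97). G2 and M phase genes were positive for 56 of 59 (0.16) and S phase genes for 41 of 45 (0.11). Of the mitochondrial lists, fusion and cristae genes were high (0.16, percentile 98.57), the mitochondrial ribosome likewise (0.12, percentile 99.95), and mitophagy genes (-0.16, percentile 0.06) and the mitochondrial genome (-0.13, percentile 0.04) were low, while fission genes (0.08, percentile 81.2) and the 75 nuclear genes of oxidative phosphorylation (0.04, percentile 50.52) were inside the range.

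Changes with Mdivi-1 in both populations were set side by side for 6799 genes at a mean of 10 TPM or more in each, with no library in common. Whether the HSCP and Ly6G+ libraries came from the same mice is not known, so the changes may not be independent. Spearman's rho across genes was 0.285 and Pearson's r 0.212, where genes are not independent replicates. Among 514 of these genes called in Ly6G+, 385 (74.9%) had the same sign in HSCP. Of 197 called higher 132 were positive in HSCP, and of 317 called lower 253 were negative, while 58.9% of all these genes were positive there.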

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

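A test of whether the change with Mdivi-1 is the same in both populations passed for 9 of the 45 lists, by limma camera on an interaction term with a preset correlation, chosen only after the results were seen. It does not establish a difference between populations: the HSCP side is 1 library against 1, so any offset particular to those libraries enters every list and their own spread was never measured. The change of the neutrophil maturation list was more positive in Ly6G+ than in HSCP (adjusted p = 2.63e-21), as were the Toll-like receptor and inflammasome list (adjusted p = 3.58e-05), the eosinophil list (adjusted p = 0.000281), the mitophagy list (adjusted p = 0.00109) and the mitochondrial genome list (adjusted p = 0.0108). The change of the B cell list was more negative in Ly6G+ (adjusted p = 2.9e-12), as were the G2 and M phase list (adjusted p = 8.56e-06), the erythroid list (adjusted p = 3.58e-05) and the S phase list (adjusted p = 0.00322). Maturation genes had a median of 0.45 in Ly6G+ and -0.02 in HSCP, and G2 and M phase genes -0.06 and 0.16. B cell genes were lower in both, at -1.32 and -0.51. With an estimated correlation 0 lists passed, where adjusted p = 0.453 was the lowest of the 9. For single genes the interaction gave 0 of 12338 past the threshold in limma, with 1398 at an unadjusted p under 0.05. The 2 residual degrees of freedom come from Ly6G+ alone.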

How the results depend on the processing

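In Ly6G+ the counts, 290 higher and 499 lower, were 104 and 114 with no expression filter, 542 and 1044 at a threshold of 0.1, and 23 and 17 when tested against a 1.5-fold change. They were 96 and 255 with all 6 libraries and 126 and 220 with a plain eBayes prior, which was added later. With replicate number as a block they were 152 and 173. The difference between the vehicle replicates and that between the Mdivi-1 replicates, taken in order of number, correlated at -0.031 across genes. Leaving out 1 library gave 17 to 116 higher and 5 to 163 lower: the total was 42 without vehicle 1, 22 without vehicle 2, 279 without Mdivi-1 library 1 and 212 without Mdivi-1 library 2. An arm of 1 library was then assumed to vary like the other group. Of the 42, 22, 279 and 212 calls, 39, 18, 235 and 191 were also main calls, and the cause of the drop was not tested. Dnm1l ran from -0.041 to 0.05 as each library was left out, was -0.03 in another of these fits, and passed in none.

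Between populations, 4156 genes were higher after median-of-ratios scaling, and 1060 higher and 2751 lower were past a 1.5-fold change. With an estimated correlation 0 lists were called in Ly6G+ (5 at an unadjusted p under 0.05, limma camera) and 0 between populations (8 at an unadjusted p under 0.05). Otherwise 10 to 13 lists were called in Ly6G+ and 26 to 40 between populations. The mitophagy list changed direction under fry (adjusted p = 0.699), and the cause was not tested.

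In HSCP the size rule gave 53 higher and 75 lower at a mean of at least 5 TPM, 15 and 23 at 20 TPM, 177 and 227 with no minimum, and 18 and 16 at a log2 ratio of 1.5. It gave 15 higher and 34 lower for protein-coding genes alone, and 15 and 29 for genes with at least 80% unique 31-mers, both added later. The relation between populations, 0.285, ran from 0.265 to 0.275 as each Ly6G+ library was left out. Fits with DESeq2, voom and total-count scaling, set out before, were not run, because they need counts.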

Other observations

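Genes of inflammatory signalling went both ways in Ly6G+ cells with Mdivi-1. In the TNF and NF-kB list 6 of 44 rose and 3 fell (adjusted over the list alone, 8 and 9; limma camera adjusted p = 0.952): interleukin-1 beta Il1b rose by 1.21 and the chemokine gene Cxcl2 by 1.15, and the chemokine gene Ccl3 fell by 1.49. Among 31 Toll-like receptor and inflammasome genes 5 rose and 2 fell (adjusted over the list alone, 8 and 3; limma camera adjusted p = 0.163), where the endotoxin co-receptor gene Cd14 rose by 1.52, the receptor genes Tlr6 and Tlr13 by 0.83 and 0.76, and Tlr9, the receptor for unmethylated DNA, fell by 0.99. Of 29 monocyte and macrophage genes 4 rose and 4 fell (adjusted over the list alone, 4 and 5), with the mannose receptor gene Mrc1 at -1.18 and the transcription factor gene Irf8 at -0.59 (limma camera adjusted p = 0.889). Among 10 plasma cell genes 2 rose and 3 fell, also adjusted over the list alone, with Mzb1, a chaperone gene of antibody secretion, at -1.84 and the IgG2b constant region Ighg2b at 1.70.

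Among stress, death and metabolic genes in Ly6G+, Plk2, a kinase gene induced by p53, rose by 1.42 (limma adjusted p = 0.0138) and the survival factor gene Mcl1 by 0.45 (limma adjusted p = 0.0134), with 2 of 25 p53 targets and 2 of 28 apoptosis regulators higher and 0 lower (adjusted over the list alone, 3 higher and 2 lower, and 2 and 0). Of 27 integrated stress response genes 2 rose and 2 fell (adjusted over the list alone, 6 and 6; after median-of-ratios scaling, 3 and 1), and of 17 hypoxia genes 2 rose and 1 fell (adjusted over the list alone, 6 and 2; after median-of-ratios scaling, 2 and 0). Among 30 antioxidant genes 1 rose, heme oxygenase Hmox1 (0.34), and 3 fell, including catalase Cat (-0.52). Adjusted over that list alone 3 rose and 5 fell, and the balance changed to 2 higher and 2 lower after median-of-ratios scaling and to 2 and 1 after upper-quartile scaling. In the NADPH oxidase list 1 of 7 fell, the gp91 subunit gene Cybb (-0.37), and 3 fell adjusted over the list alone. The glucose transporter gene Slc2a1 rose by 0.66 and hexokinase Hk2 fell by 0.48, among 25 glycolysis genes with 1 higher and 1 lower (adjusted over the list alone, 1 and 4). Of 59 G2 and M phase genes 5 fell, among them Cdc20 (-0.46) and Cenpf (-0.56), 6 fell adjusted over the list alone, and after median-of-ratios scaling 2 fell. Of 45 S phase genes 0 passed in limma, also when adjusted over the list alone.

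The tests of explanations in the remaining paragraphs were chosen only after the results were seen, also where they draw on lists fixed earlier, and the patterns are hypotheses. Of the 3 ways to split the 4 Ly6G+ libraries into pairs, 1 gave 789 or more genes, the real one, and the highest other count was 0 in limma, where those splits had 176 and 223 genes at an unadjusted p under 0.05. Any difference between treatments adds to the spread within pairs in those splits, which lowers their counts. With only 3 splits no share under 0.05 is possible, so this cannot decide whether the calls arose by chance.

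The fall of interferon-stimulated genes in Ly6G+ could come from fewer other cells in the Mdivi-1 sort. Monocyte and macrophage genes that were not higher in Ly6G+ than in HSCP had a median of -0.257 (bootstrap 95% interval -0.532 to 0.149, n = 12), against -0.439 for the interferon list, and the width of that interval keeps this open. That test covers only monocyte and macrophage genes. Medians were -1.32, -0.88, -0.59 and -0.58 for the B cell, megakaryocyte, dendritic cell, and mast cell and basophil lists. The whole monocyte and macrophage list (-0.01) and the eosinophil list (-0.002) hardly moved. Cell type lists therefore differed, which also leaves this open. Reads shared within interferon gene families could also matter. However, 49 of 57 members with at least 80% unique 31-mers had a median of -0.41 (-0.523 to -0.326), which argues against that source in these libraries. The intervals here were drawn over genes, so they carry no spread between libraries.

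The HSCP genes past the size rule may reflect how reads are assigned between similar genes. Their median was 90.5% unique 31-mers against 97.8% in random sets of genes matched on expression (n = 69 with 31-mers, one-sided permutation p = 1e-05, the smallest possible value). Of the 74 genes, 23 also differed 2-fold between Ly6G+ replicates, against 42 of 7913 others (Fisher's exact p = 6.78e-32). The first result fits that explanation, for part of the genes. The second was not matched on expression and would hold for any genes that vary between libraries, so it cannot single out read assignment.

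Fkbp5 (58.8 and 101 TPM in HSCP, log2 change 1.43 in Ly6G+) and Mt2, both chosen after their values were seen, and Per1 (1.59 in Ly6G+), Dusp1, Ddit4 and Il1r2 are known to be induced by glucocorticoids and had positive changes with Mdivi-1 in both populations, although Mt2 did not pass in Ly6G+ (0.97, limma adjusted p = 0.0742). A response to glucocorticoids could raise them, yet 19 further genes of that response had a median of 0.186 in Ly6G+ (-0.063 to 0.632; 5 higher, 1 lower) and 0.143 in HSCP (percentile 98.41, n = 18), and an interval that includes 0 keeps this open. Handling before the sort could raise such genes as well: the immediate early list, which includes Dusp1, had a median of -0.018 in Ly6G+ (-0.209 to 0.256, n = 21) with 4 members higher and 4 lower, and 0.173 in HSCP (percentile 99.78), and members that go both ways keep this open. More mature neutrophils in the HSCP Mdivi-1 library would raise the maturation list. Its median there was -0.021 (-0.124 to 0.145 over genes, n = 32). The list as a set did not rise, which argues against that source within these libraries, without a replicate check. The 6 genes of this pattern had a median of 0.986 and a lowest value of 0.772. They were noticed for their positive changes, and Il1r2 is also in the maturation list, so the gap between these medians adds nothing to that.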
